A study of Mus musculus with 9 samples.

How the data were processed

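The read counts per gene were used as deposited by the authors, in a single table of whole numbers with 38720 genes named by symbol and 20 libraries. The authors' notes on the processing before deposition name TopHat2 2.0.10, Bowtie2 2.2.3, BWA 0.7.5, Trimmomatic 0.32, featureCounts, SAMtools, Picard 1.105 and MACS2 2.0.10, and the mouse builds mm10 and GRCm38. Which of these tools made the counts is not spelled out tool by tool, and the gene annotation and the strand setting are not given in the sources used here. Genes are therefore identified by symbol only, and no genomic positions are given. At least 1 count was found for 29693 genes. Chromatin samples of the same series (FLAG immunoprecipitation, input and ATAC) were not used here.

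Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest), with TMM factors, the filterByExpr filter (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05, and every edgeR test was two-sided. The deletion comparison used its own 10 libraries without pairing by library number, although 8 of them correlated best with their own number. The transgenic comparisons used their 10 libraries in a single fit with 4 groups, because the mTEC groups hold 2 libraries each. A dose comparison over both subsets tested the mean of the cTEC and mTEC differences, and an interaction tested whether these differ. CPM, the standard depth-scaled count of edgeR, uses the raw totals and is given as mean and SD over libraries. Log2 fold changes are fitted values with a prior count of 0.125, given with the standard error (SE). Where all libraries of a group had 0 counts, the fold is a lower bound against 3 counts over the group. Intervals and floors of this kind cover counting error only.

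Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over all lists of a comparison. Camera with an estimated correlation and fry, directional and mixed, served as alternatives. The 19 gene lists were thymocyte attraction and commitment, cTEC identity, mTEC identity, tissue-restricted antigens, tuft-like TEC, MHC class I pathway, MHC class II pathway, proteasome subunits, autophagy, cell cycle, p53 targets and apoptosis, epithelial keratins and junctions, keratinocyte differentiation, TEC transcription factors, WNT, BMP and FGF signalling, interferon response, immediate early and stress genes, cholesterol biosynthesis and oxidative phosphorylation. The 7 marker lists covered thymocytes and T cells, macrophages and dendritic cells, B cells, fibroblasts and mesenchyme, endothelium, erythroid cells and sex-linked transcripts. Of 379 list members 377 were in the table, and of 84 markers 83. The cTEC identity list shares 4 members with the attraction list (Dll4, Ccl25, Cxcl12, Kitl) and 3 with the MHC class II list (Prss16, Cd83, Ctsl), so these results are not independent. No marker of another cell type is a member of a second list.

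The comparisons, tests, threshold, lists and the rule for named genes were fixed before the data were examined. By that rule Foxn1, Psmb11, Dll4, Ccl25, Cxcl12, Prss16, Cd83 and Ctsl are named in every comparison. The deletion and the dose comparison in cTEC also take the 10 largest changes in each direction, and the other comparisons 5. These came from genes past the threshold with a mean CPM of at least 2 and no overlap between the CPM of the groups, leaving out predicted genes, ribosomal pseudogenes and receptor segments. From each list up to 2 members of smallest adjusted p per direction serve as examples, and members that did not pass are given with values. A few genes that the rule names are not reported here. Subset-specific lists for the deletion comparison are the 200 genes of smallest p in each direction between the homozygous subsets.

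A simulation drew new counts from the group means and gene-wise spread of the same libraries. Known changes were put into a small share of the genes, and the compared groups were otherwise equal. Genes were drawn independently, so variation shared between genes is missing, and far fewer genes changed than in the real dose comparisons. The shares below hold for the simulated counts and may not carry over. At 1.5-fold, 2-fold and 4-fold the test recovered 32.8%, 61.2% and 95.5% of changed genes with the deletion design, 74.6%, 92.5% and 98.5% with the cTEC dose design, and 58.2%, 85.1% and 97.0% with the mTEC dose design. The share of false calls was 3.82%, 7.81% and 11.1% in these 3 designs. It was 8.23% for the interaction, 10.9% for the dose over both subsets, and 10% and 12.8% for the subset comparisons in homozygous and heterozygous mice. Those shares are above the nominal 5% for every design with the transgenic libraries. Among 100 unchanged lists per design, 1 to 3 had a camera p under 0.05, and 2 to 9 a fry p under 0.05. Those lists were random sets of independently drawn genes, so they do not test the preset correlation on real lists.

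The p-values measure the spread between libraries, and nothing in the sources used here says that these come from separate animals. The sex-linked transcript Xist ran from 2.10 to 563 CPM in control, 473 to 1209 in deleted and 216 to 659 in homozygous cTEC. Y-linked transcripts summed to 71.0 to 254.5, 45.9 to 171.8 and 101 to 173.5 CPM there. This argues against splits of a single RNA sample in these groups. In the other groups the spread may be technical.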

Results

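Polyadenylated RNA of sorted thymic epithelial cells (TEC) from mice was sequenced as 20 libraries in 6 groups. Cortical cells (cTEC) were sorted as CD45-negative, EpCAM-positive, MHC class II-positive, Ly51-positive cells, and medullary cells (mTEC) as cells binding the lectin UEA1 in place of Ly51. Foxn1 encodes the forkhead transcription factor required for thymic epithelial development, and nude mice lack its function. A transgenic set carries a Foxn1 transgene on the nude background, with 3 heterozygous and 3 homozygous cTEC libraries and 2 libraries each of heterozygous and homozygous mTEC. The deletion set holds 5 cTEC libraries in which Cre, switched on by doxycycline, removed exons 7 and 8 of floxed Foxn1, and 5 control libraries from doxycycline-treated mice without Cre, all at 72 h. Totals ran from 20719630 to 22372633 counts per library. A mean of 20168 genes had counts in heterozygous and 19972 in homozygous cTEC, 23779 in heterozygous and 25410 in homozygous mTEC, 20716 in control and 21123 in Foxn1-deleted cTEC. Libraries of a group differed by more than counting error in every group. The chi-square per gene between pairs ran from 30.4 to 145.8 in control cTEC and from 4.50 to 5.98 in homozygous cTEC.

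Foxn1 itself was counted in every library. Mean CPM was 454 ± 91.6 in control cTEC and 434 ± 81.1 in Foxn1-deleted cTEC (SD, n = 5 each). It was 1364.5 ± 103 in homozygous and 1165.6 ± 38.0 in heterozygous cTEC (n = 3 each), and 318 ± 15.5 in homozygous and 495 ± 9.83 in heterozygous mTEC (n = 2 each). The count covers the whole gene, including exons the deletion leaves in place and any transcript of the nude allele. It therefore measures neither the deletion nor the transgene alone.

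**Figure D1:**
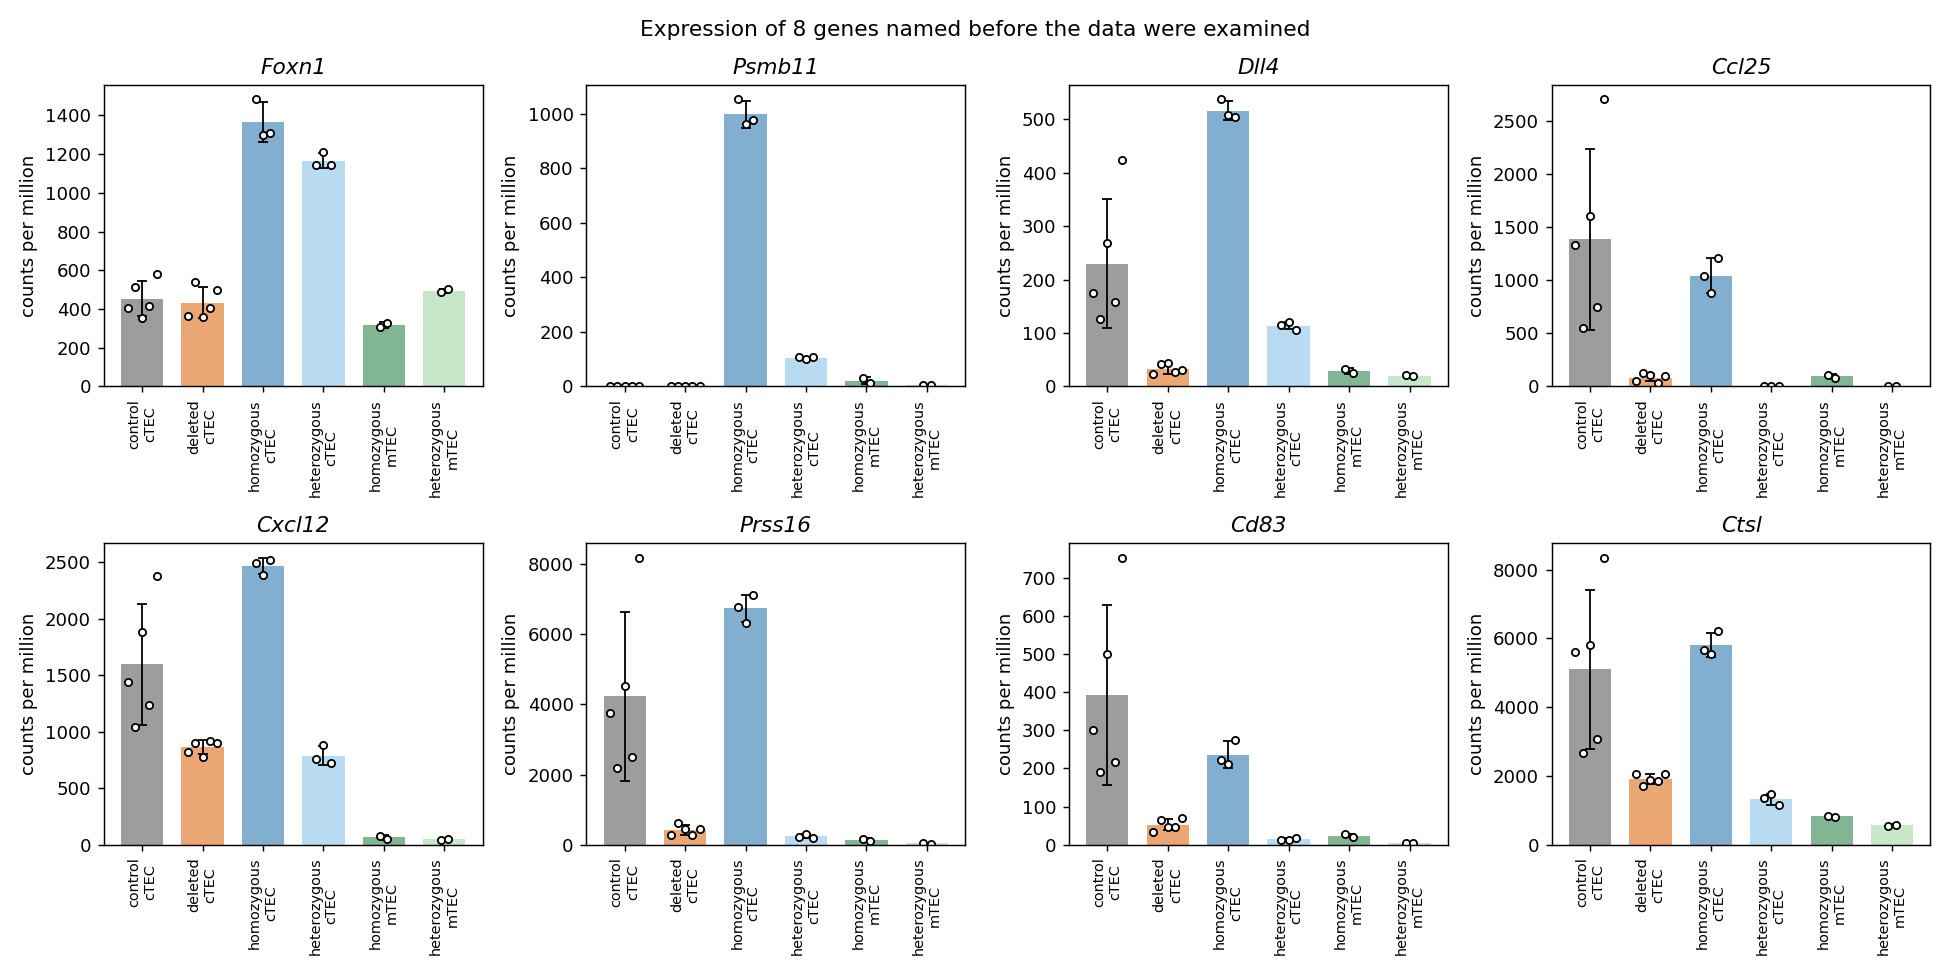
Mean CPM (bars, linear axes from 0) of 8 genes fixed in advance in the 6 groups, with SD as error bars and single libraries as points. Ccl25 averaged 84.2 CPM in Foxn1-deleted against 1387.5 in control cTEC and 6.04 in heterozygous against 1044 in homozygous cTEC, while Foxn1 stayed at 434 and 454 CPM in the deletion set.

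The deletion comparison asks which cTEC transcripts depend on Foxn1 at 72 h after doxycycline. Of the 8 genes fixed in advance, 5 fell: Ccl25, Dll4, Prss16, Cd83 and Ctsl. Ccl25, a chemokine for progenitors, was at 84.2 ± 37.1 CPM in Foxn1-deleted and 1387.5 ± 852 in control cTEC (SD, n = 5 each; log2 fold change -4.09 ± 0.52 SE, adjusted p = 0.00934). Dll4, the Notch ligand that commits progenitors to the T lineage, was at 33.2 ± 9.15 against 230.1 ± 120.4 CPM (-2.83 ± 0.35). Prss16, the thymus-specific serine protease, was at 413 ± 139 against 4226 ± 2404 CPM (-3.40 ± 0.41), a 10.5-fold difference. Cd83, which stabilises surface MHC class II, fell by 2.94 ± 0.40 log2 and Ctsl, the cathepsin that trims class II ligands, by 1.46 ± 0.30. For all 5 of these genes each deleted library was below each control library, and the same held for Cxcl12. Cxcl12, a chemokine that retains progenitors, was at 863 ± 62.7 against 1595 ± 538 CPM and did not pass (-0.92 ± 0.21, adjusted p = 0.0574). Foxn1 did not pass (-0.09 ± 0.16, adjusted p = 0.783), nor did Psmb11, the beta5t subunit of the thymoproteasome, at 0.319 ± 0.297 against 0.920 ± 0.555 CPM (-1.55 ± 0.69, adjusted p = 0.250). Psmb11 had only 9 to 40 counts per control library and 0 to 15 per deleted library. That is too few for the missing call to show whether it depends on Foxn1. The labels name the doxycycline-responsive activator of these mice after this subunit, as beta5t-rtTA.

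Larger falls than that of Ccl25 were found outside the fixed genes, as in Gper1, a G protein-coupled estrogen receptor, at 4.46 ± 2.51 against 100.1 ± 52.7 CPM (-4.53 ± 0.49, adjusted p = 0.00789). Tbata, a stromal gene of the thymus, was at 78.9 ± 31.5 against 1317 ± 978 CPM (-4.11 ± 0.57). Ppp1r27 (-4.23), Slc22a7 (-4.17), Neu2 (-4.14), Shank2 (-4.01), Crip3 (-3.81), Fer1l6 (-3.81) and Umodl1 (-3.76) fell as well. Rises were smaller. Figf, the vascular growth factor VEGF-D, was at 5.52 ± 1.83 against 1.60 ± 0.68 CPM (1.77 ± 0.35, adjusted p = 0.0332), and Ptger4, a prostaglandin E2 receptor, at 60.9 ± 14.5 against 27.7 ± 8.46 CPM (1.12 ± 0.23). Mettl24 (1.65), Serpinb8 (1.61), Lhfp (1.53), Cck (1.26), Zbtb7c (1.19), Edn1 (1.17), Abcg1 (1.07) and Ahnak2 (1.04) rose too.

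By the edgeR quasi-likelihood test, 43 genes were higher and 257 lower of 15224 tested, and 20 and 188 of these changed at least 2-fold. The unadjusted p was under 0.05 for 2944 genes. The counts of higher and lower genes rest on the method and on single libraries. DESeq2 gave 327 higher and 781 lower, limma-voom 15 and 89, and a replicate block by library number 398 and 822. A gene that did not pass here may therefore pass with that block, and the list tests were not run with it. Genes lower numbered 156 without control library 1, 732 without control 2, 64 without control 3 and 450 without control 4, and 46, 96, 123, 27 and 67 without deleted libraries 1 to 5. Genes higher numbered 188 without control 2, 1 without control 3, 13 without deleted 2, 11 without deleted 3, and 0 without deleted 1, 4 or 5 by the same edgeR test. Of 26 called genes named by the rule, 15 lost the call without at least 1 library. All 10 named genes that rose lost it without control 3 or deleted 1, 4 or 5, and some of them without control 1, 4 or 5 or deleted 2 or 3. Ctsl, Irf8 and Wipi1 lost it without control 1 or 3 or any deleted library, Umodl1 without control 3 or deleted 1, 4 or 5, and Cd83 without deleted library 4. Ccl25, Dll4, Prss16, Tbata and Gper1 kept it in all 10 such fits. Over the fits without a single library the median log2 fold change of the 257 genes stayed between 83.1% and 109.8% of its value with every library.

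The cTEC identity list fell as a group, with 8 of 19 tested members down and none up (median -0.85, camera adjusted p = 1.12e-07). The number that fell was 12 adjusted over the list alone. The call was lost at adjusted p = 0.836 with an estimated correlation. The 8 members were Tbata, Prss16, Ccl25, Cd83, Dll4, Slc46a2 (-2.19 ± 0.30), Ctsl and Ly75, an endocytic receptor (-0.85 ± 0.18). Ly75 lost its call without control 1 or 3 or any deleted library, and Slc46a2 without deleted library 4. Pax1 (-0.25), Krt8 (-0.81), Krt18 (-0.77) and Enpep, which encodes the Ly51 antigen of the sort (-0.03), did not pass. Of the attraction list 3 of 20 members fell: Ccl25, Dll4 and Flt3l, a progenitor growth factor (-1.26 ± 0.27), which kept its call only when no library or control 2 was left out. There 4 fell and 2 rose adjusted over the list alone, and the list was not called (adjusted p = 0.977, with a positive median of 0.14 and a negative mean). Il7 (-0.14) and Kitl (-0.16), cytokines for early thymocytes, did not pass, and neither did the Notch ligands Dll1 (0.43) and Jag1 (0.60).

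The MHC class II list was not called either (adjusted p = 0.977, median 0.08 against a negative mean). Its 3 of 20 members that fell were Prss16, Cd83 and Ctsl, none of which is a class II chain, and 3 fell and 1 rose adjusted over the list alone. The class II chains H2-Aa (0.03), H2-Ab1 (0.12) and H2-Eb1 (0.30), the invariant chain Cd74 (0.05) and the class II transactivator Ciita (-0.15) did not pass. Irf8 (-1.26 ± 0.28) among TEC transcription factors and Wipi1 (-1.02 ± 0.21) in autophagy fell as single members, with calls lost in 7 of the 10 fits without a library. These became 1 up and 2 down among transcription factors and 1 down in autophagy adjusted over the list alone. Neither list was called (adjusted p = 0.836 and 0.977).

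Some lists were called although no member passed over all genes. Proteasome subunits had a median of -0.26 (31 tested, camera adjusted p = 4.63e-10), with Psmb5, the constitutive catalytic subunit, at -0.76 and Psmb4 at -0.77. Cholesterol biosynthesis had a median of -0.43 (19 tested, adjusted p = 1.71e-06), with Idi1, an isomerase of the pathway, at -0.97. Oxidative phosphorylation had a median of -0.21 (21 tested, adjusted p = 1.71e-06), with Uqcrc2 at -0.29. Adjusted over the list alone, 11, 9 and 3 members of these lists fell. Each call was lost at adjusted p = 0.836 with an estimated correlation. The interferon response had a median of 0.19 (20 tested, adjusted p = 0.0132, and adjusted p = 0.865 with an estimated correlation), with 3 members up adjusted over the list alone, among them Irf7 (0.39).

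Markers of other cells moved in the same libraries. The thymocyte list had a median of -0.83 with 0 of 19 members past the threshold (camera adjusted p = 0.00158, and adjusted p = 0.879 with an estimated correlation). Its summed CPM spanned 129 to 717 in deleted and 140 to 992 in control libraries. The fibroblast list had a median of 0.67 with 0 of 13 past the threshold (adjusted p = 0.00997, and adjusted p = 0.836 with an estimated correlation). Its sum was 1243 to 1955 CPM in deleted and 551 to 1236 in control libraries, and Dcn, a matrix proteoglycan, had a log2 fold change of 0.85 (adjusted p = 0.132). The remaining lists had no member past the threshold over all genes and were not called: mTEC identity (median 0.02), tissue-restricted antigens (0.04), tuft-like TEC (0.08), MHC class I (0.01), cell cycle (-0.01), p53 targets (0.03), keratinocyte differentiation (0.42), WNT, BMP and FGF signalling (0.17), immediate early genes (0.38), macrophages (0.33), B cells (-0.13), endothelium (0.19) and sex-linked transcripts (-0.68). Epithelial keratins and erythroid markers were not called either (adjusted p = 0.628 and 0.989). These lists had 2 rises and 3 falls in WNT, BMP and FGF signalling, 2 and 1 in keratinocyte differentiation, 2 and 2 in keratins, 1 and 2 in MHC class I, 1 rise in mTEC identity and 1 fall each in tuft-like TEC and p53 targets adjusted over the list alone. The median and mean differed in sign for mTEC identity, tissue-restricted antigens, MHC class I and cell cycle.

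**Figure D2:**
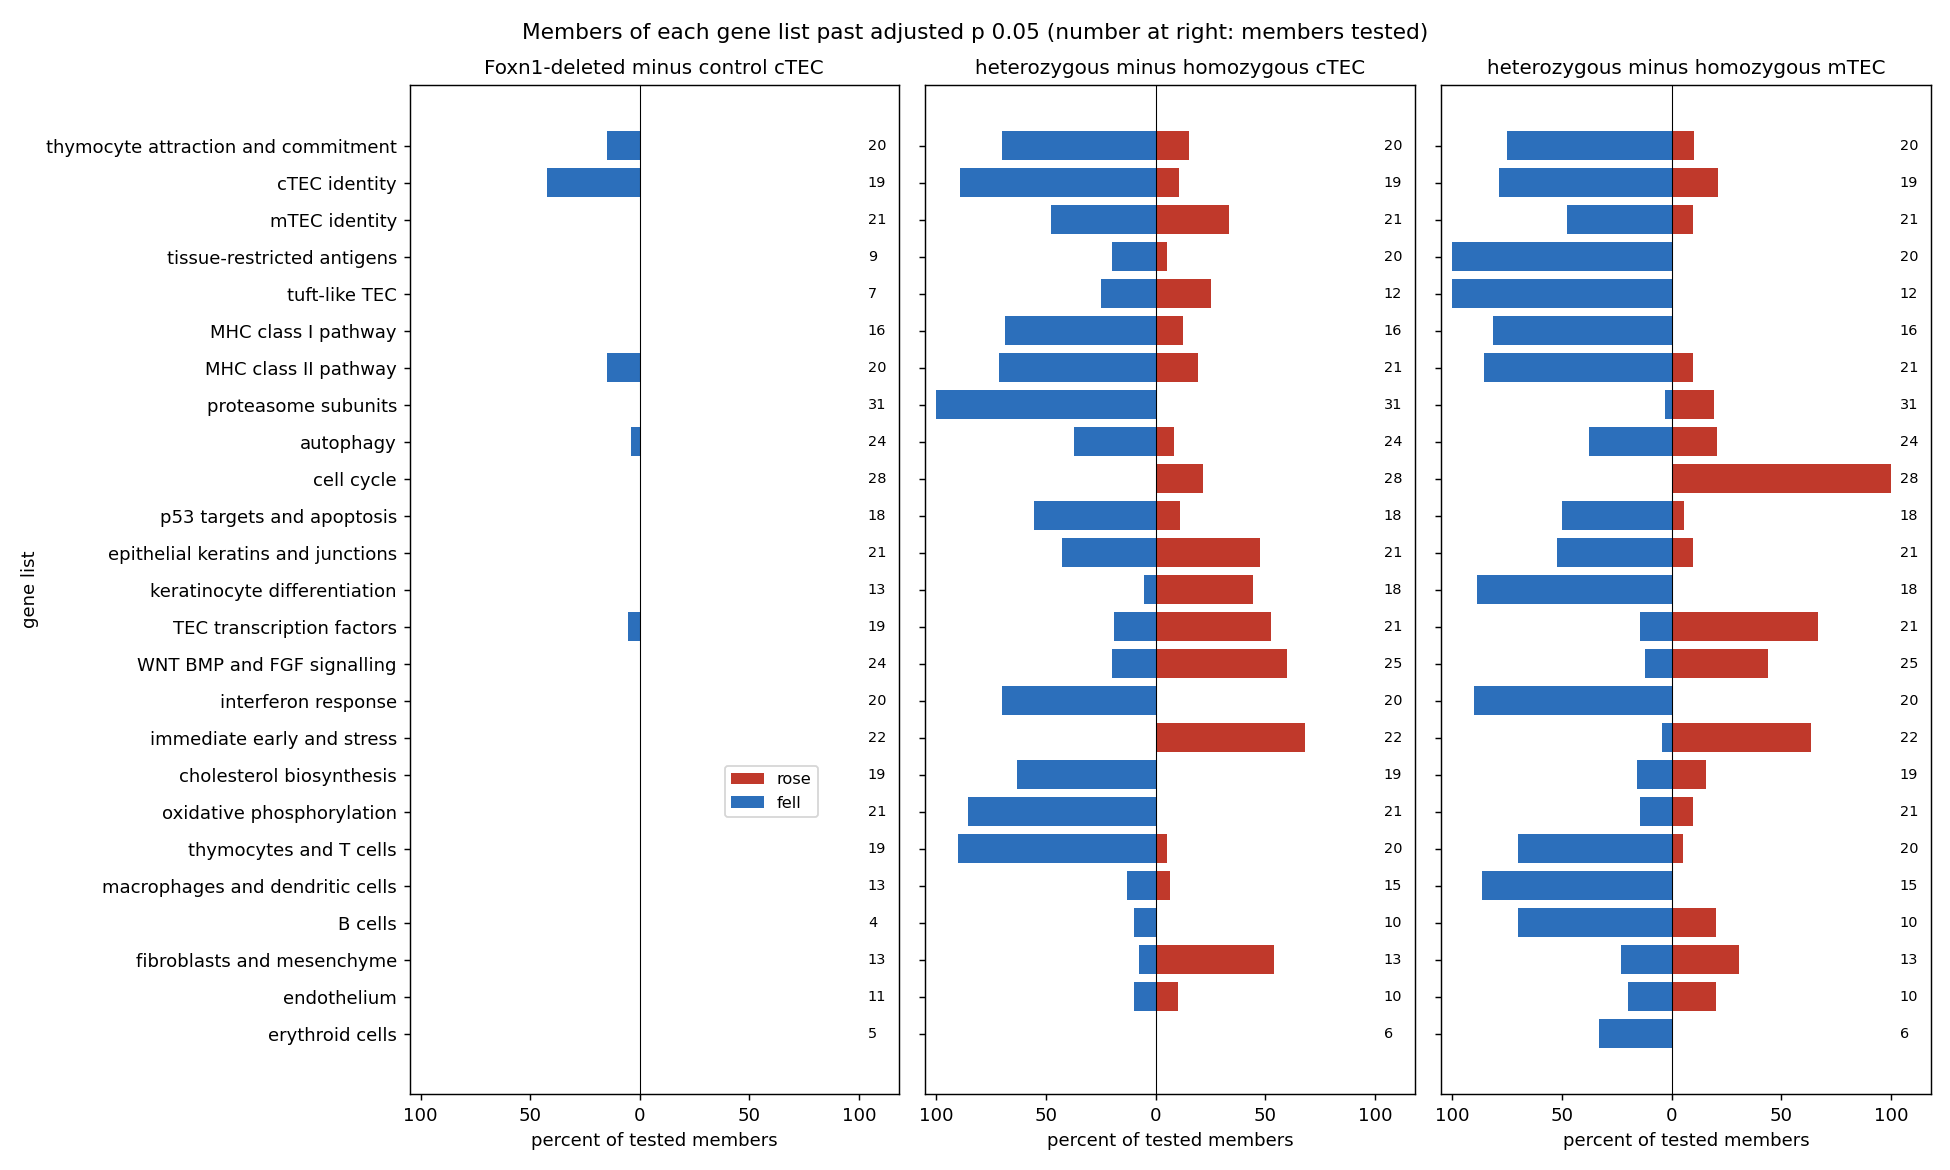
Percent of tested members of each list that rose (right) or fell (left) past an adjusted p of 0.05 in the deletion comparison, the cTEC dose comparison and the mTEC dose comparison, with the number tested at the right of each panel. In the cTEC dose comparison 31 of 31 proteasome subunits fell, and in the mTEC dose comparison 28 of 28 cell cycle genes rose and 20 of 20 tissue-restricted antigens fell.

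The dose comparison in cTEC asks what changes with fewer copies of the Foxn1 transgene. All 8 fixed genes were lower in heterozygous cTEC. Foxn1 was 1.28-fold lower (-0.36 ± 0.06, adjusted p = 4.45e-04, n = 3 each). Ccl25 was at 6.04 ± 0.347 against 1044 ± 168 CPM, a 189-fold difference (-7.57 ± 0.16, adjusted p = 2.47e-12). Psmb11 was at 105 ± 3.88 against 997 ± 49.0 CPM (-3.38 ± 0.18), Prss16 at 247 ± 65.5 against 6737 ± 390 CPM (-4.90 ± 0.22) and Dll4 at 114 ± 7.33 against 517 ± 18.3 CPM (-2.31 ± 0.08). Cd83 (-4.13 ± 0.15), Ctsl (-2.26 ± 0.09) and Cxcl12 (-1.78 ± 0.12) fell too. Fgf14, a channel-modulating relative of the growth factors, was at 0.888 against 157 CPM (-7.59), and Slc22a7 (-7.61), Itgbl1 (-6.22), Cdh8 (-5.58), Fxyd2 (-5.52), Crip3 (-5.44), Stpg1 (-5.04) and Ppp1r27 (-4.98) completed the largest falls with Ccl25. Rises were led by Fam107a at 36.5 against 0.340 CPM (6.58 ± 0.32), and by Otog (6.49), Sox10 (6.37), Abca8a (6.35), Kif19a (5.99), Igf2 (5.81), Sln (5.79), Sim1 (5.72) and Epyc (5.70).

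In this comparison 4024 genes were higher and 4201 lower of 19222 tested, 1570 and 1006 of them at least 2-fold. Without normalization factors, a scaling chosen after seeing the data, the median of all genes shifted by 0.13 log2. The split then became 5931 higher and 2859 lower, so 32.5% of changed genes were lower in place of 51.1%.

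Of the cTEC identity list 17 of 19 members fell and 2 rose (median -1.53, camera adjusted p = 3.22e-11, and adjusted p = 0.238 with an estimated correlation). The simple-epithelial keratins Krt8 (-1.53) and Krt18 (-1.54) and the thymic regulator Pax1 (-0.65) were among those that fell, and Scx, a tendon transcription factor, rose (2.06). The attraction list had 14 of 20 down and 3 up (median -0.67, adjusted p = 0.00173, and adjusted p = 0.238 with an estimated correlation), with the Notch ligand Jag1 up (1.40). All 31 proteasome subunits fell (median -0.80, adjusted p = 6.50e-21, and adjusted p = 0.260 with an estimated correlation), as in Psmb4 (-1.48) and the ATPase subunit Psmc2 (-1.20). The MHC class I list had 11 of 16 down and 2 up (adjusted p = 0.00288, and adjusted p = 0.543 with an estimated correlation). Within it the immunoproteasome subunits Psmb10 (-1.68) and Psmb9 (-1.06) fell, while Psmb8 (0.95) and the activator Psme1 (0.93) rose. The MHC class II list had 15 of 21 down and 4 up (adjusted p = 6.91e-04, and adjusted p = 0.527 with an estimated correlation), with Ctsz (1.32) and March8, a ligase that removes class II from the surface (0.66), up. The counts of these 5 lists were the same adjusted over the list alone.

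Interferon response genes fell (14 of 20, none up, median -0.73, camera adjusted p = 2.37e-05, and adjusted p = 0.543 with an estimated correlation). Oxidative phosphorylation genes fell (18 of 21, median -0.30, or -0.16 without normalization factors, adjusted p = 3.00e-06, and adjusted p = 0.527 with an estimated correlation), and so did cholesterol biosynthesis genes such as Sqle (-0.87) (12 of 19, adjusted p = 2.42e-04, and adjusted p = 0.560 with an estimated correlation). Immediate early genes rose in 15 of 22 cases with none down (median 1.04, adjusted p = 5.15e-05, and adjusted p = 0.543 with an estimated correlation). Egr1 was at 1269 against 292 CPM (1.99) and Dusp1, a MAP kinase phosphatase, at 74.5 against 9.21 CPM (2.88). WNT, BMP and FGF signalling had 15 of 25 up and 5 down (median 0.56, adjusted p = 0.00415, and adjusted p = 0.527 with an estimated correlation), with Wnt5a (3.28) and Fgfr1 (2.51) up and Wnt4 (-0.68) and the WNT antagonist receptor Kremen1 (-0.88) down. Keratinocyte differentiation had 8 of 18 up and 1 down (adjusted p = 0.0279, and adjusted p = 0.335 with an estimated correlation), with Spink5, an epidermal protease inhibitor, up (2.87) and the desmoglein Dsg1a down (-1.11, a call lost without heterozygous library 2 or 3 or homozygous library 1). Its median was 0.60, or 0.80 with members at or under 3 counts in a group set to their bound. Adjusted over the list alone, 16 interferon, 19 oxidative phosphorylation and 13 cholesterol genes fell, 15 immediate early genes rose and 1 fell, 15 signalling genes rose and 6 fell, and the keratinocyte counts were the same.

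Lists that were not called in cTEC include epithelial keratins, with 10 of 21 up and 9 down. There the basal keratins Krt5 (547 ± 47.9 against 95.3 ± 11.5 CPM, 2.39 ± 0.10), Krt14 (2.16) and Krt15 (4.87) rose while Krt8 and Krt18 (-1.54) fell. mTEC identity had 7 of 21 up and 10 down, with Cd40 down (-1.98), and TEC transcription factors 11 of 21 up and 4 down, with Gata3 up (2.54) and Irf8 down (-1.40). Cell cycle had 6 of 28 up and 0 down, p53 targets 2 of 18 up and 10 down, autophagy 2 of 24 up and 9 down, tuft-like TEC 3 of 12 up and 3 down, and tissue-restricted antigens 1 of 20 up and 4 down. Of mTEC identity genes 8 rose and 11 fell, of cell cycle genes 5 rose and of transcription factors 5 fell adjusted over the list alone, and the other counts were the same.

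Thymocyte markers were lower in heterozygous cTEC: 18 of 20 fell and 1 rose (median -3.03, camera adjusted p = 7.19e-09, and adjusted p = 0.335 with an estimated correlation). Ptprc, which encodes the CD45 antigen excluded in the sort, was at 1.06 against 8.85 CPM (-3.19), Tcf7 fell (-1.85) and Cd28 rose (0.47), a call lost without heterozygous library 1 or 3 or any homozygous library. Their summed CPM was 68.8 to 98.0 in heterozygous and 154 to 219.9 in homozygous libraries. Fibroblast markers had 7 of 13 up and 1 down (median 0.74, adjusted p = 0.00203, and adjusted p = 0.260 with an estimated correlation), with Dcn at 153 against 30.2 CPM (2.21), Lum up (4.51) and Postn down (-0.68, a call lost without homozygous library 2). Macrophage markers had 1 of 15 up and 2 down, B cell markers 0 of 10 up and 1 down, endothelial markers 1 of 10 up and 1 down, and erythroid and sex-linked markers none past the threshold.

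The overlap of the deletion and the cTEC dose comparison asks whether the genes that fall after Foxn1 deletion are those that fall at lower transgene dose, in experiments that share no libraries. Of the 257 genes lower after deletion, 231 were lower in heterozygous cTEC as well and 11 were higher, with 68.7 shared genes expected if the lists were independent (odds ratio 25.8, 95% interval 17.1 to 40.4, one-sided Fisher exact p = 4.26e-103, 15133 genes tested in both). Of the 42 genes higher after deletion, 23 were higher and 4 lower in heterozygous cTEC (10.1 expected, odds ratio 3.85, interval 2.00 to 7.48, one-sided Fisher exact p = 1.76e-05). The shared genes that fell include Gper1 (-4.53 after deletion and -1.78 by dose), Ppp1r27 (-4.23 and -4.98), Neu2 (-4.14 and -4.51), Tbata (-4.11 and -3.84), Ccl25 (-4.09 and -7.57), Shank2 (-4.01 and -3.39), Crip3 (-3.81 and -5.44) and Prss16 (-3.40 and -4.90). Log2 fold changes correlated across genes at a Spearman rho of 0.556 and a Pearson r of 0.531, and genes are not independent replicates.

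**Figure D3:**
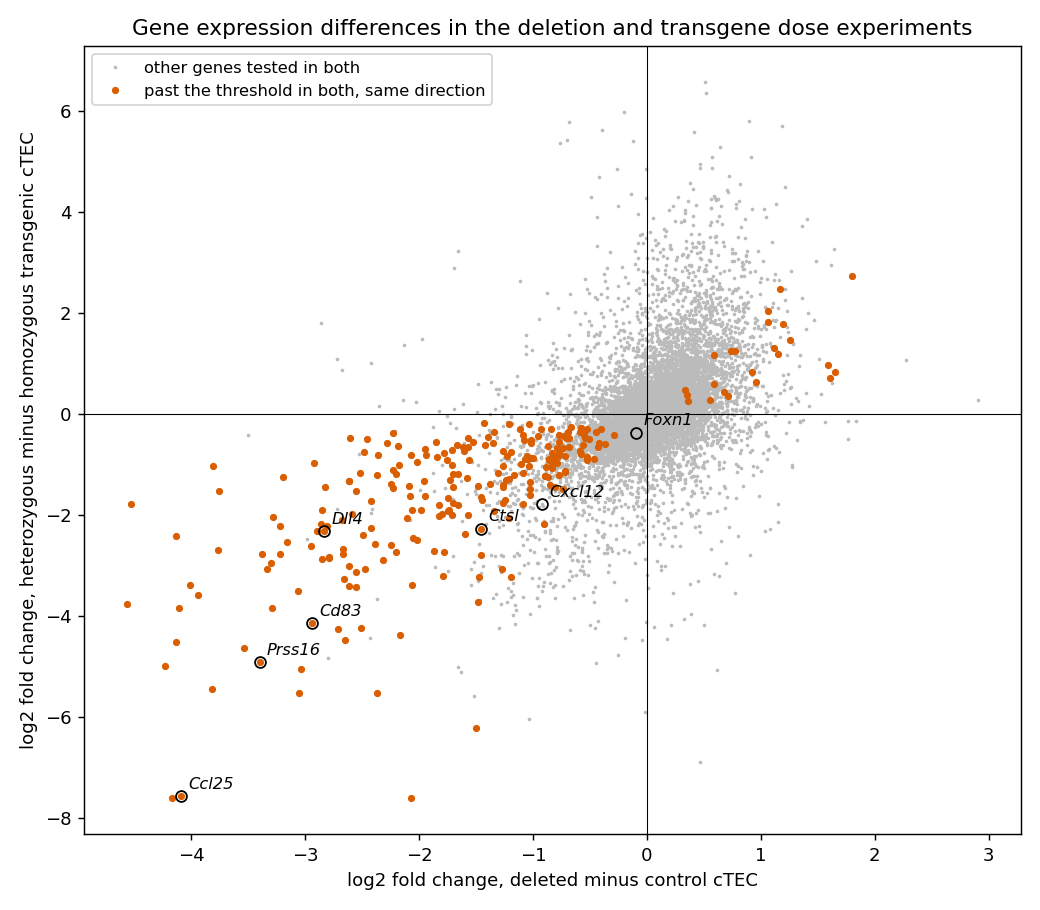
Log2 fold change of Foxn1-deleted against control cTEC (horizontal axis) and of heterozygous against homozygous cTEC (vertical axis), 1 point per gene tested in both, orange where past the threshold in the same direction in both comparisons, with 7 of the genes fixed in advance circled and named. The 231 genes lower in both include Ccl25 at -4.09 and -7.57 and Prss16 at -3.40 and -4.90.

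The dose comparison in mTEC asks the same of medullary cells. Foxn1 was higher in the libraries labelled heterozygous (0.66 ± 0.08, adjusted p = 1.68e-05, n = 2 each), against the direction of the labelled dose. An exchange of these labels would turn every direction of the mTEC dose comparison and change the interaction and the values over both subsets. It would also exchange the mTEC libraries of both comparisons with cTEC and change the subset-specific lists taken from them. The fixed genes Ccl25 (5.30 against 96.3 ± 19.6 CPM, -4.16 ± 0.18), Psmb11 (4.34 against 21.3 ± 11.6 CPM, -2.27 ± 0.30), Cd83 (-2.23 ± 0.22), Prss16 (34.6 against 137 ± 53.4 CPM, -1.96 ± 0.25), Ctsl (-0.54 ± 0.11), Dll4 (-0.49 ± 0.11) and Cxcl12 (-0.46 ± 0.16, adjusted p = 0.0227) were lower there, as they were in heterozygous cTEC. Cxcl12 lost its call without heterozygous or homozygous library 1. The largest falls by the rule were Gip, an incretin hormone (-5.94), Cyp2d12 (-5.67), Fabp9 (-5.55), Timd2 (-5.09) and Muc3, an intestinal mucin (-5.07), which are transcripts of other tissues. The largest rises were Fosb at 135 ± 9.23 against 6.69 CPM (4.36 ± 0.56), Fos (3.14), the heat shock gene Hspa1a (3.12), Pth2 (2.88) and Bmp4 (2.70).

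The tissue-restricted antigen list, peripheral genes that mTEC display to developing T cells, fell as a whole: 20 of 20 members (median -2.40, camera adjusted p = 1.33e-10, and adjusted p = 0.0791 with an estimated correlation). Ins2 (-4.36), Mup4 (-3.84), Csn1s2a (-3.67) and Csn2 (205 against 994 CPM, -2.25) were among them. Keratinocyte differentiation had 16 of 18 down (median -2.05, adjusted p = 2.40e-07, and adjusted p = 0.0791 with an estimated correlation), with Spink5 at 10.7 against 70.9 CPM (-2.71). All 12 tuft-like TEC genes fell (median -1.37, adjusted p = 1.67e-06, and adjusted p = 0.226 with an estimated correlation), with the taste-receptor G protein Gnat3 at 87.7 against 301 CPM (-1.76) and the tuft regulator Pou2f3 at -1.22. mTEC identity had 10 of 21 down and 2 up (median -0.24, or -0.37 with RLE factors, adjusted p = 0.0170, and adjusted p = 0.501 with an estimated correlation). In it the costimulators Cd86 (-3.75) and Cd80 (-1.24) and the chemokine Ccl22 (-3.37) fell, Tnfrsf11a, the receptor RANK (0.23), rose with a call lost without any library but homozygous 2, and Aire, the regulator of antigen display (-0.11 ± 0.12, adjusted p = 0.446), Relb (-0.01), Krt5 (-0.19) and Krt14 (-0.13) did not pass.

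Every cell cycle gene tested rose (28 of 28, median 0.92, camera adjusted p = 1.38e-08, and adjusted p = 0.453 with an estimated correlation), with Top2a at 196 against 99.9 CPM (0.99 ± 0.11) and Mcm7 at 119 against 64.7 CPM (0.91). Of the p53 targets 9 of 18 fell and 1 rose (adjusted p = 0.0441, and adjusted p = 0.453 with an estimated correlation), with the cycle inhibitor Cdkn1a down (-1.81) and the survival gene Bcl2 up (0.51). TEC transcription factors had 14 of 21 up and 3 down (adjusted p = 0.00159, and adjusted p = 0.453 with an estimated correlation), with Pax9 up (0.84) and Irf8 down (-0.76). Immediate early genes had 14 of 22 up and 1 down (adjusted p = 0.00131, and adjusted p = 0.576 with an estimated correlation), with Jun (2.48) and Egr1 (2.37) up and the chaperone Hspa5 down (-0.45). The interferon response had 18 of 20 down (median -1.39, adjusted p = 4.49e-06, and adjusted p = 0.453 with an estimated correlation), with Usp18 at 75.5 against 221 CPM (-1.53) and the chemokine Cxcl9 at -1.41. MHC class I had 13 of 16 down (adjusted p = 6.63e-04, and adjusted p = 0.453 with an estimated correlation), with H2-D1 at -1.16 and the loading factor Tapbp at -0.95. MHC class II had 18 of 21 down and 2 up (adjusted p = 4.49e-06, and adjusted p = 0.363 with an estimated correlation), with H2-Eb1 (-0.99) down and March8 (0.42) and Ciita (0.27, a call lost without heterozygous library 2 or homozygous library 1) up. The cTEC identity list had 15 of 19 down and 4 up (median -0.56, adjusted p = 0.00886, and adjusted p = 0.453 with an estimated correlation). The attraction list had 15 of 20 down and 2 up (adjusted p = 0.00103, and adjusted p = 0.115 with an estimated correlation), with Ccl20 down (-2.83) and the Notch ligands Jag2 (1.05) and Dll1 (0.92) up. Adjusted over the list alone, 16 attraction and 19 interferon genes fell, 15 immediate early genes rose, 4 transcription factors fell, and the other counts of these lists were the same.

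Not called in mTEC were proteasome subunits (6 of 31 up, 1 down), autophagy (5 of 24 up, 9 down), epithelial keratins (2 of 21 up, 11 down, with the claudin Cldn4 at -2.17), WNT, BMP and FGF signalling (11 of 25 up, 3 down), cholesterol biosynthesis (3 of 19 up, 3 down) and oxidative phosphorylation (2 of 21 up, 3 down). Adjusted over the list alone, these became 5 and 0 for proteasome subunits, 3 and 11 for keratins, 1 and 1 for cholesterol biosynthesis and 0 and 1 for oxidative phosphorylation. Macrophage and dendritic cell markers were lower in the same libraries: 13 of 15 fell (median -2.10, camera adjusted p = 1.84e-05, and adjusted p = 0.226 with an estimated correlation). Lyz2, the myeloid lysozyme, was at 87.5 against 507 CPM (-2.51), and the summed CPM was 144 to 148 in heterozygous and 616 to 722 in homozygous libraries. Which cells gave these markers, or the Cd86, Cd80 and Ccl22 counts that fell with them, was not tested. Thymocyte markers had 14 of 20 down and 1 up (adjusted p = 0.0216, and adjusted p = 0.623 with an estimated correlation), with Ptprc at -1.48 and 15 down adjusted over the list alone. B cell markers had 7 of 10 down and 2 up (adjusted p = 0.0441, and adjusted p = 0.453 with an estimated correlation), with Ighm down (-2.20) and Igkc up (1.97). Fibroblast markers had 4 of 13 up and 3 down, endothelial markers 2 of 10 up and 2 down, erythroid markers 0 of 6 up and 2 down, and sex-linked transcripts 1 of 5 up, and none of these lists was called.

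In mTEC 5550 genes were higher and 5922 lower of 19222 by the edgeR test, 687 and 3561 of them at least 2-fold. Under the labels as given most changes of at least 2-fold were therefore falls, and with exchanged labels they would be rises. With RLE factors in place of TMM the median of all genes shifted by -0.13 log2 and the split became 3911 higher and 7082 lower, or 64.4% lower in place of 51.6%. Of the 20 tissue-restricted antigens tested, the list median was -2.40 or lower under every scaling.

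**Figure D4:**
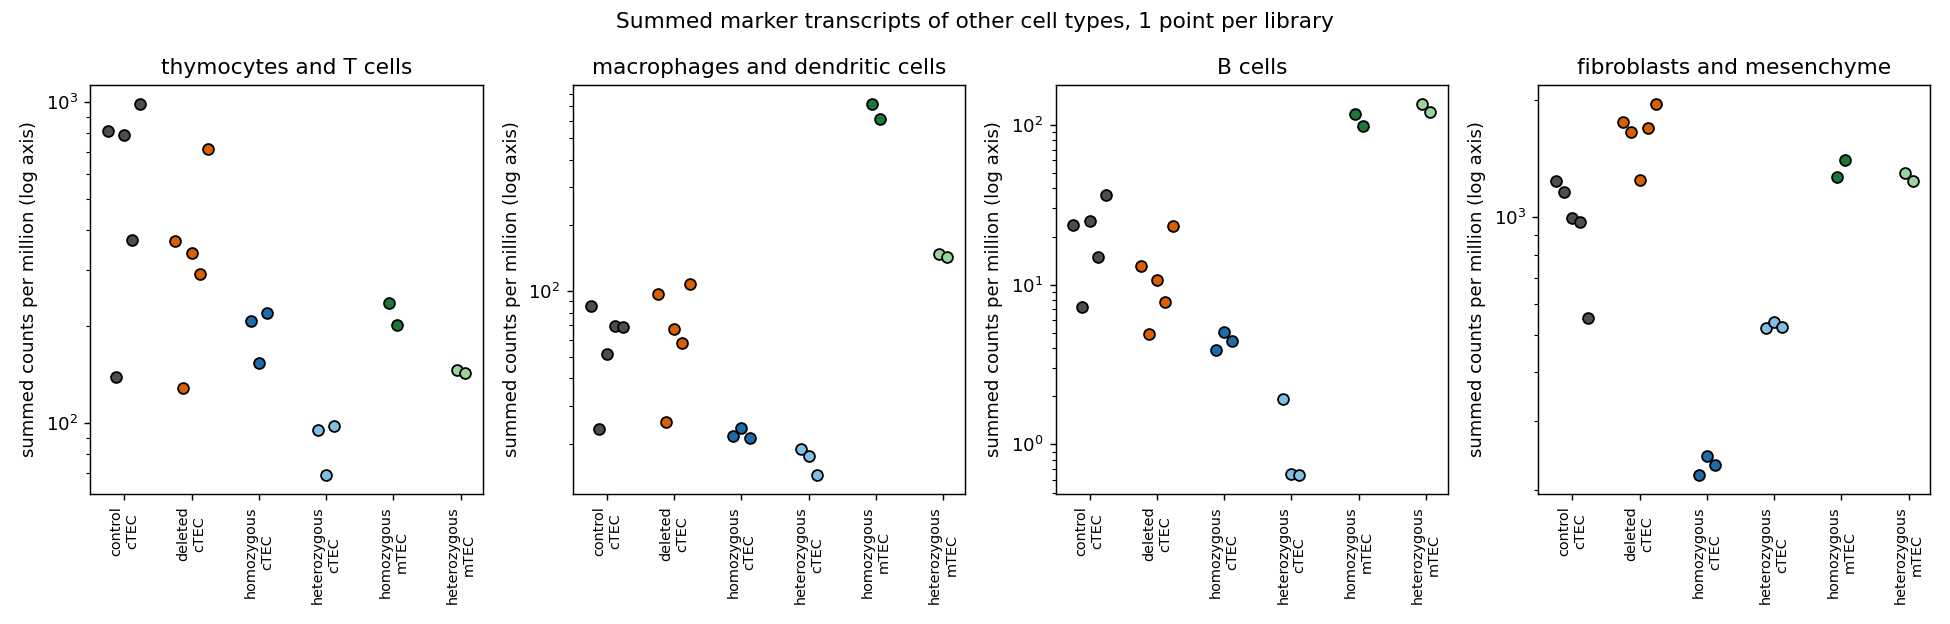
Summed CPM of marker genes of thymocytes, macrophages and dendritic cells, B cells and fibroblasts (log axis) in each library of the 6 groups, 1 point per library. Macrophage markers sum to 616 to 722 CPM in homozygous and 144 to 148 in heterozygous mTEC, and thymocyte markers span 140 to 992 CPM in control cTEC.

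The interaction asks whether the dose difference is unequal in the subsets. It was for all 8 fixed genes, each with a positive value, meaning a difference more positive in mTEC than in cTEC: Ccl25 (3.41 ± 0.25), Prss16 (2.95 ± 0.31), Cd83 (1.90), Dll4 (1.82 ± 0.14), Ctsl (1.72), Cxcl12 (1.32), Psmb11 (1.11 ± 0.37, adjusted p = 0.0264, lost without heterozygous mTEC library 2) and Foxn1 (1.02 ± 0.10, adjusted p = 5.55e-06). Under the mTEC labels as given, proteasome subunits differed most uniformly (30 of 31 positive, median 0.85, camera adjusted p = 1.03e-15, and adjusted p = 0.444 with an estimated correlation), followed by cell cycle genes (24 of 28 positive, median 0.66, adjusted p = 7.58e-06, and adjusted p = 0.682 with an estimated correlation). Keratinocyte differentiation was negative in 12 of 18 members (adjusted p = 5.23e-07, and adjusted p = 0.0732 with an estimated correlation), with Spink5 at -5.58. In these lists 30, 27 and 13 members differed adjusted over the list alone. With exchanged mTEC labels each interaction would be the value over both subsets times -2. Over both subsets the medians were -0.38 for proteasome subunits, 0.53 for cell cycle and -0.53 for keratinocyte differentiation. Proteasome subunits would then keep a positive interaction median, while the cell cycle and keratinocyte medians and the Foxn1 value would change sign. Over all genes 4848 values were positive and 3314 negative of 19222. The count is sensitive to scaling: with RLE factors it was 3403 and 3925, with upper-quartile factors 3310 and 4019, and without factors 3101 and 4123, as the median of all genes shifted by -0.13, -0.14 and -0.16 log2.

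Over both subsets together, 5591 genes were higher and 4344 lower in heterozygous libraries. Without factors 36.1% of the changed genes were lower in place of 43.7%, and with RLE factors 53.5% (4550 higher and 5235 lower). With exchanged mTEC labels this test becomes that of the interaction with its sign turned, so 3314 genes would be higher and 4848 lower. Under the labels as given, the named falls were Ccl25 (-5.86 ± 0.12, adjusted p = 4.02e-12), Slc22a7 (-5.57), Chi3l4 (-5.14), Sis, the intestinal sucrase (-5.11), and Fgf14 (-4.95). With exchanged mTEC labels each value would become the negative of the interaction divided by 2, and Ppp1r27 (interaction 5.30) would stand ahead of Ccl25 (3.41). Fam107a (4.20), Fosb (3.84), Abca8a (3.67) and Kif19a (3.60) rose. Prss16 (-3.43), Cd83 (-3.18), Psmb11 (-2.83), Dll4 (-1.40), Ctsl (-1.40) and Cxcl12 (-1.12) fell, and Foxn1 was slightly higher (0.15 ± 0.05, adjusted p = 0.0242), a call lost without heterozygous mTEC library 2, homozygous mTEC library 1 or homozygous cTEC library 2 or 3. Among lists the interferon response (19 of 20 down, median -1.07, camera adjusted p = 6.68e-10, and adjusted p = 0.287 with an estimated correlation), MHC class II (17 of 21 down, 2 up, adjusted p = 1.17e-08, and adjusted p = 0.266 with an estimated correlation) and immediate early genes (17 of 22 up, 1 down, adjusted p = 5.37e-05, and adjusted p = 0.385 with an estimated correlation) changed in both subsets taken as a mean. In all, 18 of 26 lists were called. All 20 interferon genes fell adjusted over the list alone.

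The comparisons of mTEC with cTEC also test the sort labels. In homozygous mice Foxn1 was lower in mTEC (318 against 1364.5 CPM, -2.34 ± 0.08, adjusted p = 7.78e-12, 2 mTEC and 3 cTEC libraries). Prss16 (-5.87), Psmb11 (-5.79), Cxcl12 (-5.47), Dll4 (-4.40), Ccl25 (-3.68), Cd83 (-3.57) and Ctsl (-3.04) were lower in mTEC, while Fezf2, a regulator of antigen display (8.63), the milk casein Csn2 (994 against 2.07 CPM, 8.65), Tnfrsf11a (5.57) and Krt14 (4.14) were higher. Pdyn, the dynorphin precursor, was at 29.3 CPM in mTEC and at 0 counts in cTEC, at least 629.9-fold higher, and Prokr1 (-6.04), Galr2 (-5.78) and Pkhd1l1 (-5.55) led the other direction. All 21 mTEC identity, 20 tissue-restricted, 12 tuft-like and 18 keratinocyte genes tested were higher in mTEC (camera adjusted p = 1.40e-07, 3.08e-07, 1.58e-05 and 7.20e-06). With an estimated correlation these gave adjusted p = 0.276, 0.276, 0.305 and 0.132. The cTEC identity list had 16 of 19 lower and 3 higher (adjusted p = 1.58e-05, and adjusted p = 0.276 with an estimated correlation). Proteasome subunits were lower in 27 of 31 cases and cell cycle genes in 27 of 28 (adjusted p = 7.30e-06 and 8.75e-05), with Top2a at 99.9 against 178 CPM (-1.08). Those calls were lost at adjusted p = 0.529 and 0.742 with an estimated correlation. All 15 macrophage and all 10 B cell markers were higher in mTEC (adjusted p = 2.02e-04 and 9.67e-04, and adjusted p = 0.305 for both with an estimated correlation), and 9 of 13 fibroblast markers, with Rgs5, a pericyte gene, at 935 against 4.12 CPM (7.58). None of these counts changed when adjusted over the list alone.

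Between these homozygous subsets 8303 genes were higher in mTEC and 7577 lower. Upper-quartile factors shifted the median of all genes by 0.25 log2 and gave 9610 higher and 5700 lower, total counts alone gave 9581 and 5724, and RLE factors shifted the median by 0.18.

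In heterozygous mice 7763 genes were higher in mTEC and 6080 lower, with a shift of 0.11 under upper-quartile factors. Foxn1 was at 495 against 1165.6 CPM (-1.32 ± 0.07, adjusted p = 2.68e-09). Psmb11 (-4.68), Cxcl12 (-4.15), Prss16 (-2.92), Dll4 (-2.58), Cd83 (-1.67) and Ctsl (-1.32) were lower in mTEC. Ccl25 did not pass, at 5.30 against 6.04 CPM (-0.27 ± 0.20, adjusted p = 0.241). Fezf2 (9.52) and Csn2 (9.27) were higher, and Gal3st2, a sulfotransferase, was at least 517.9-fold higher against 0 counts in cTEC. Scn1a (-6.03), Emilin3 (-5.64), Colgalt2 (-5.37), Mrc2 (-5.35) and Col8a2 (-4.91) were the largest differences in the other direction. The mTEC identity (21 of 21 higher), tuft-like (12 of 12) and tissue-restricted (18 of 20 higher, 1 lower) lists were called (camera adjusted p = 5.80e-10, 2.30e-05 and 6.36e-05), and with an estimated correlation they gave adjusted p = 0.233, 0.352 and 0.233. Proteasome subunits were higher in 22 of 31 cases and lower in 1 (adjusted p = 0.0268, and adjusted p = 0.830 with an estimated correlation), the reverse of the homozygous subsets under the mTEC labels as given. WNT, BMP and FGF signalling genes were lower in 17 of 25 cases and higher in 5 (adjusted p = 0.00422, and adjusted p = 0.478 with an estimated correlation). All 10 B cell and 10 endothelial markers tested were higher in mTEC (adjusted p = 0.00112 and 0.0248), calls lost at adjusted p = 0.233 and 0.813 with an estimated correlation. The signalling counts became 6 higher and 17 lower adjusted over the list alone, and the others were the same.

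The subset-specific genes link both experiments. Of the 200 genes most clearly higher in cTEC than in mTEC of homozygous mice, 57 fell after Foxn1 deletion and none rose (median -0.40, camera adjusted p = 2.92e-23, adjusted p = 0.0715 with an estimated correlation, fry adjusted p = 0.00383). Of the 200 higher in mTEC, 0 rose and 0 fell by the edgeR test, with a median of 0.20 (camera adjusted p = 0.00226, adjusted p = 0.550 with an estimated correlation, fry adjusted p = 0.499). With lists of 500 genes, 84 cTEC genes fell and 1 rose, and 3 mTEC genes rose and 2 fell. With 200 genes chosen between the heterozygous subsets, 31 cTEC genes fell and none rose (median -0.12, camera adjusted p = 9.70e-06, adjusted p = 0.136 with an estimated correlation). Of the 200 mTEC genes chosen that way 0 rose and 1 fell, and the list was not called (median 0.09, camera adjusted p = 0.322).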

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

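The tests in this part were chosen before the results were seen, except the list medians without genes of very low count. Each item is a difference between the subsets in the effect of transgene dose, or a library far from the others of its group. In the deletion experiment 42 group measures were examined for a library far from the others of its group, and 1 stood out. Deleted library 3 had 4.50% of counts on ribosomal protein genes, with the nearest deleted library at 3.96%. Chance marks about 1 in 20 such groups, so 1 of 42 is no more than chance gives.

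The dose difference was unequal in mTEC and cTEC for 31 items by the edgeR interaction test or by camera. The interaction is the difference in mTEC minus that in cTEC. The fixed genes were all positive: Foxn1 at 1.02, Psmb11 at 1.11, Dll4 at 1.82, Ccl25 at 3.41, Cxcl12 at 1.32, Prss16 at 2.95, Cd83 at 1.90 and Ctsl at 1.72. Foxn1 was lower in heterozygous cTEC (-0.36) and higher in heterozygous mTEC (0.66). The other fixed genes were lower in heterozygous libraries of both subsets, and the fall was larger in cTEC. Some were low in homozygous mTEC libraries 1 and 2: Psmb11 at 29.5 and 13.1 CPM, and Prss16 at 174 and 98.8. In homozygous cTEC they were at 961 to 1053 and 6330 to 7107 CPM. Whether such counts in the mTEC libraries come from mTEC themselves was not tested.

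The interactions below hold for the mTEC labels as given. With exchanged labels each would be the value over both subsets times -2, which puts Ccl25 (-5.86 over both) ahead of the genes named here. Ppp1r27 was at 5.30, with a dose difference of -4.98 in cTEC and 0.31 in mTEC, where it did not pass. Fgf14 followed at 5.29 (-7.59 in cTEC and -2.30 in mTEC) and Slc22a7 at 4.07 (-7.61 and -3.54), both lower in heterozygous cells of each subset. Pcdh15, a hair cell cadherin, was at 4.89 (-3.30 and 1.59) and Nsg2, a neuronal vesicle gene, at 4.15 (-3.39 and 0.76), with opposite directions in the subsets. Negative interactions were found for Elf5, an epithelial ETS factor, at -7.36 (7.12 in cTEC and -0.24 in mTEC, where it did not pass), Bpifb9b at -7.16, a call lost without heterozygous cTEC library 1, and Cadm2, a synaptic adhesion gene, at -6.72 (5.30 and -1.43). These 3 genes had at most 3 counts over the homozygous cTEC libraries, so their fitted values depend on the prior count. Krt13, a keratin of stratified mucosa, was at -6.71 (3.97 and -2.74) and Ccl11, the eotaxin chemokine, at -6.44 (3.83 and -2.61).

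Lists with positive medians were cTEC identity at 1.17, proteasome subunits at 0.85, cell cycle at 0.66, cholesterol biosynthesis at 0.44, oxidative phosphorylation at 0.31 and thymocyte markers at 1.63. Lists with negative medians were keratinocyte differentiation at -2.33, macrophage and dendritic cell markers at -1.66, tuft-like TEC at -1.11, fibroblast markers at -0.94, interferon response at -0.57, WNT, BMP and FGF signalling at -0.28 and epithelial keratins and junctions at -0.17. Under the other 3 scalings every one of these medians kept its sign, but small ones moved: oxidative phosphorylation to between 0.15 and 0.18, cholesterol biosynthesis to between 0.28 and 0.32, keratins and junctions to between -0.33 and -0.30, and WNT, BMP and FGF signalling to between -0.44 and -0.41. Left to members with more than 3 counts in each group, the medians were -2.08 for keratinocyte differentiation, -1.41 for tuft-like TEC and -0.25 for WNT, BMP and FGF signalling. Cell cycle genes rose in mTEC (28 of 28) and in part in cTEC (6 of 28). Proteasome subunits fell in cTEC (31 of 31), and in mTEC 6 of 31 rose and 1 fell. Every one of these 13 calls was lost with an estimated correlation, where the adjusted p ran from 0.0732 for keratinocyte differentiation to 0.695 for interferon response, cholesterol biosynthesis and oxidative phosphorylation.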

How the results depend on the processing

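Leaving out both libraries numbered 2, the Y-linked and thymocyte covariates and scaling by total counts only were chosen after seeing the data, and the other settings before. The deletion counts depend on the tool and on single libraries, and 1 fit of all libraries moved the counts for dose in cTEC, dose in mTEC, the interaction and lower genes over both subsets. DESeq2 moved higher genes for dose in mTEC and the interaction, but not the counts for dose in cTEC. In the deletion comparison (43 higher, 257 lower) DESeq2 gave 327 and 781, limma-voom 15 and 89, and all 20 libraries in 1 fit 536 and 1005. A replicate block gave 398 and 822. Same-numbered libraries correlated across genes at 0.0853 to 0.754 with group means removed, and other pairs at -0.621 to 0.328. Since 1 same-numbered pair lay below 0.1 the numbers were not taken as pairs. The other same-numbered pairs correlated at 0.353 to 0.754, and 8 of 10 libraries correlated best with their own number. The numbers may therefore mark a shared source of variation, which the unpaired counts, list tests and splits leave out. In the transgenic set same-numbered libraries correlated at -0.0656 to 0.0748. Without both libraries numbered 2 the counts were 69 and 405, and with the thymocyte covariate 113 were higher. Leaving out single libraries gave 0 to 188 higher and 27 to 732 lower. The lowest lower count came without deleted library 4 and the highest without control library 2, and a higher count of 0 came without deleted library 1, 4 or 5. Of the 257 lower genes, 255 remained with DESeq2, 89 with limma-voom, 257 with the block, 257 in 1 fit of all libraries and 249 without both libraries numbered 2. DESeq2 gave 3430 higher genes for dose in mTEC and 3177 positive genes for the interaction. All libraries in 1 fit, which mixes both experiments in 1 estimate of spread, gave 2427 higher and 2435 lower genes for dose in cTEC, 3246 and 3573 in mTEC, 2344 and 1796 for the interaction, and 2638 lower for dose over both subsets. Scaling by total counts only gave 3101 positive interaction genes. Genes shared by deletion and dose in cTEC (231 lower, 23 higher) numbered 505 and 98 at an adjusted p under 0.1, 647 and 175 with DESeq2, 357 and 43 without both libraries numbered 2, and 696 and 233 with the replicate block. Beyond those looser or smaller by construction, the cause was not tested.

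The lists called by camera numbered 7 in the deletion, 13 in cTEC dose, 16 in mTEC dose, 12 and 13 in the homozygous and heterozygous subset comparisons, 13 in the interaction and 18 for dose over both subsets. An estimated correlation left 0 in each of the 7 comparisons. Fry called 1 list in the deletion and 20 in the homozygous subset comparison. Mixed fry called 3 in the deletion, 22 in cTEC dose, 25 and 24 in the homozygous and heterozygous subset comparisons, and 21 in the interaction. Fry does not compare a list with other genes, so its counts answer another question. For cTEC-specific genes in the deletion the adjusted p was 0.0715 with an estimated correlation. For mTEC-specific genes it was 0.550 with an estimated correlation, 0.499 by fry and 0.322 with lists from heterozygous mice.

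Among named genes 1 value reversed: Cdh5, an endothelial marker, went from 1.38 to -0.12 in the mTEC dose comparison without heterozygous mTEC library 1, and to 2.11 without library 2. Each leaves 1 library in that group, assumed to vary like the others. Of 665 values of named genes under alternatives in the deletion 539 kept direction and side of the threshold, 117 lost the call and 9 gained it. Of 1581 values in cTEC dose 45 lost it, and of 1408 in mTEC dose 130 did. In the deletion design 32.8% of changes of 1.5-fold were recovered in simulation, which limits what a missing call can show.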

Other observations

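Both thymocyte-marker tests, the Aire test and the macrophage test were chosen after the results were seen, and the Y-linked and thymocyte covariates and the fits without libraries numbered 2 were added after seeing the data. Some genes changed the same way in all 3 comparisons, although Foxn1 counts did not: 99 genes were lower after deletion in cTEC, in heterozygous cTEC and in heterozygous mTEC, and 8 were higher in all 3, of 15133 genes tested. Besides Ccl25, Prss16, Cd83 and Dll4 they include Slc22a7, an organic anion transporter (-4.17, -7.61 and -3.54), Crip3 (-3.81, -5.44 and -2.97), Neu2, a sialidase (-4.14, -4.51 and -1.97), Tbata (-4.11, -3.84 and -1.54) and Gch1, the enzyme that starts tetrahydrobiopterin synthesis (-3.06, -3.49 and -0.62). Gch1 was chosen after its values were seen. Of the 257 genes lower after deletion, 106 were lower in heterozygous mTEC and 67 were higher there (57.1 expected if independent, odds ratio 2.51, 95% interval 1.93 to 3.24, one-sided Fisher exact p = 4.27e-12). Of the 42 higher after deletion, 13 were higher and 15 lower in heterozygous mTEC (14.8 expected, one-sided Fisher exact p = 0.769). With exchanged mTEC labels the 106 and 67 would change places, and so would 13 and 15, so the 3-way counts rest on the labels as given and were not tested beyond the pairs. The dose differences of cTEC and mTEC shared 1455 lower genes, with 1294.3 expected and 972 of opposite direction, and 1752 higher genes, with 1161.9 expected.

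The first pattern is the set of 257 genes lower after deletion. Of 100 splits of the 10 libraries only the real one gave as many genes (300 against at most 1). This argues against chance where libraries can be exchanged freely. Since 8 of 10 libraries correlated best with their own number, that may not hold, and splits within numbers were not run. The groups differed in sex-linked transcripts: Xist averaged 348 ± 207 CPM in control and 855 ± 294 in deleted libraries (SD). With a Y-linked covariate 208 of the 257 lower calls and 20 of the 43 higher calls were kept. By the median alone the mix of sexes is argued against for the lower genes. The Y-linked covariate left their median fold at 109% of its value (bootstrap over genes 102% to 113%). The libraries numbered 2 are argued against too, since without them the median fold was at 110% (106% to 113%). These intervals resample the called genes with the 10 libraries held fixed, so they leave out the spread between libraries. Thymocyte RNA stays open, since a thymocyte covariate left 81.9% (76.9% to 84.8%), an interval that reaches below the 80% set in advance. Among same-numbered libraries the marker sum was lower in the deleted one in 5 of 5, although the ranges of the groups overlap. On the other side, 201 of the 257 calls were kept with the thymocyte covariate. Thymocyte markers also had a median of only -0.83 against -1.62 for the 257 genes, which were chosen for passing the threshold. Loss of Foxn1, which the design names, was not tested apart from these.

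The other splits bear on the transgenic set. For dose in cTEC there are 10 splits of the 6 libraries, of which 1 gave as many genes (8225 in the real split, 0 at most in the others), too few splits for a share under 0.05. For dose over both subsets 1 of 60 splits gave as many genes (9935 against at most 8162), so a chance split of the libraries is argued against. The highest other split keeps the real cTEC labels and exchanges the mTEC labels.

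The second pattern is the presence of thymocyte transcripts in cTEC libraries, although the sort excluded CD45-positive cells. A carry-over of thymocyte RNA in 1 proportion may explain it in the control libraries. There the 20 markers correlated at a mean pairwise r of 0.909 over the 5 libraries, 18 reached a mean of 2 CPM and Tcf7 was highest (125 CPM). Other cells carried over together with thymocytes would give the same correlation. In heterozygous cTEC the markers did not keep 1 proportion: Cd28 rose while most fell, and made up 34.0 CPM of a mean sum of 87.2. Blood or mixed stroma stays open: in the cTEC dose comparison B cell, macrophage, endothelial and erythroid markers had a median of -0.91 (-0.75 with genes at or under 3 counts set to their bound) against -3.03 for thymocyte markers, but 14 of the 41 were at or under 3 counts in a group, which excludes nothing. Fibroblast markers did not fall with them there (median 0.74), which goes against mixed stroma in that comparison. The control libraries give no clear answer. The fibroblast sum was lowest (551 CPM) in control library 5, where thymocyte markers sum highest (992). It was highest (1236 CPM) in control library 1, where thymocyte markers also sum high (816). In control library 2, where thymocyte markers sum lowest (140 CPM), so do those of macrophages (23.5), B cells (7.29), endothelium (8.39) and erythroid cells (0.182), and deleted library 2 is the lowest of its group in all 5.

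The third pattern is the fall of tissue-restricted antigens in heterozygous mTEC (20 of 20, median -2.40). Fewer Aire-expressing cells are argued against, since Aire was at -0.11 (SE 0.12), a value seen before that test was chosen. The choice among the scalings tried is argued against, since the list median nearest to 0 was -2.40. The other scalings shifted the median of all genes by only -0.02 to -0.13 log2, so this outcome could be foreseen. Scalings beyond these were not tested. Macrophage and dendritic cell markers fell as well, despite the CD45-negative sort (13 of 15, median -2.10), so carry-over of these cells could account for S100a8 and S100a9. The other 18 members, transcripts of other tissues, fell too (100%), which goes against carry-over as their source. That share was already fixed by the 20 of 20 seen before, so it is no separate test. The labelled transgene dose, a shift in mTEC maturation or composition, and exchanged mTEC labels, which the Foxn1 counts (0.66) would go with, stay open and untested. Ccl25, Prss16 and Psmb11 were lower in the libraries labelled heterozygous in both subsets. Whether their counts in the mTEC libraries come from mTEC themselves was not tested.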
